A study of Mus musculus with 6 samples.

How the data were processed

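Neural stem cells from the cortex of CD1 mouse embryos at embryonic day 14.5, cultured with 10 ng/ml bFGF, had been infected with a lentivirus carrying a short hairpin RNA. It was either a control hairpin (sh-control) or a hairpin against all proteins of the Quaking gene Qk (sh-Qk). The cells were collected 6 days after infection, per the labels. Qk encodes the Qki proteins, RNA-binding proteins that regulate splicing and the fate of messenger RNAs. There were 3 libraries per group, made with a poly(A) mRNA kit that does not mark strand, so reads of a gene and of an overlapping antisense gene cannot be told apart. The labels do not say that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. TopHat and the mouse build mm9 are named in the submitters' processing notes. The versions, the counting tool, the annotation and the read length are not given in the sources used here.

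Each library had a gene table and a table of alternative splicing events. The gene table deposited by the authors gives, per gene, a tag value and an RPKM value. The RPKM was recomputed from the tag value, the exon length and the sum of the tag values. The deposited tag values are estimated counts, and they are weighted. Of the values below 2550, 89.0% to 90.0% were exact multiples of 255. Therefore 255 was taken as the weight of 1 uniquely aligned read end, and smaller remainders as read ends that align to several places. This weight was inferred from the values. All tag values were therefore divided by 255 and rounded down to whole read ends, which lost at most 0.00187% of the tag sum of a library. The 2 ends of a read pair appeared to be counted separately, since even multiples of 255 prevailed, so an alternative used a divisor of 510. Depth after the division was 190575293 to 219965280 read ends in genes per library. The event tables deposited by the authors list 35003 events with an estimated count for each of 2 isoforms and, for cassette exons, the 2 inclusion junctions and the skipping junction, whose order along the gene is not stated. Cassette exons had 6796607 to 7913006 junction reads per library.

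Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05), with no block. CPM, edgeR's counts scaled to depth, are means over the 3 libraries, with the SD. Percent spliced in was the mean of the 2 inclusion junctions divided by that mean plus the skipping junction. Cassette exons with at least 10 junction reads in every library were tested with the same edgeR test on inclusion against skipping reads, with a coefficient for each library, and were called at an adjusted p under 0.05 and a difference of at least 10 percentage points. Other event types were tested in the same way on the 2 isoform counts, adjusted within each type. The sequence positions in an event name gave the exon length as end minus start: 93.8% of the tested events then had an annotated exon of that length in the gene, against 11.2% with 1 nucleotide more. The annotation was GENCODE M21 on GRCm38, a build other than mm9, and was used for names, exon lengths, coding status by length and 3' UTR sequence, never for coordinates.

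The comparison, the tests, 19 gene lists from textbook knowledge and the rule for named genes were fixed before the data were examined. The rule took Qk and the 10 genes with the largest fold change in each direction (adjusted p under 0.05, at least 5 CPM in a group, CPM ranges that do not overlap, no clone or predicted name). It also took up to 4 members of each list with the smallest adjusted p and the 10 called cassette exons with the largest difference in each direction (at least 20 junction reads in every library, 1 event per gene). Last, it took every tested event of Qk, up to 4 called genes of each list, and the 5 largest called events of each other type. Lists were tested on expression with limma 3.58.1 camera at a preset correlation of 0.01 and, on exons, with a two-sided Fisher's exact test against the genes with a tested cassette exon. Both were adjusted over the lists, on exons over those with at least 5 tested genes. Serpina3h belongs to a family of near-identical genes, and H2-K1 and H2-D1 are paralogs, so their values are uncertain. A few members that the rule took are not reported here.

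The alternatives were other size factors, DESeq2 1.42.0, limma-voom, other filters and thresholds, limma on log2(RPKM + 1) and log2(RPKM + 0.1), a replicate block and each library left out in turn. For exons they were also other coverage minimums, a single inclusion junction, the isoform counts as deposited, which include the exon body, limma on the logit of percent spliced in with 0.5 added to each count, and Fisher's exact test on summed counts. The divisor of 510, a log2 fold minimum of 0.5, 1 event per exon, 1 dispersion for all events and list tests on the limma logit calls were chosen after seeing the data. Replicates were not duplicates: chi-square per degree of freedom between libraries of a group was 3.83 to 22.6. The tests were tested on simulated data with 200 changed features. A simulation of the gene test of sh-Qk against sh-control covered 14443 genes. Of 98 changes of 1 and 97 changes of 0.5 on the log2 scale, 90.8% and 76.3% were recovered, with 21 false calls. In the data 54.2% of the genes tested were called, so the scaling and the rate of false calls may differ from the simulation. Over 8771 cassette exons, 98% of differences of 40 points, 56% of 20 points and 8% of 10 points were recovered, with 2 false calls. For exons, recovery was counted by the adjusted p and the direction, and false calls by the adjusted p. The minimum of 10 points was not applied in the simulation. Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining tests and the plots.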

Results

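RNA was measured by sequencing in cultured mouse cortical neural stem cells 6 days after infection with a control hairpin or with a hairpin against Qk, in 3 libraries per group. The comparison of sh-Qk with sh-control asks which transcripts and which exons change when the Qki proteins are depleted. The sh-control libraries held 219965280, 216198359 and 197427136 read ends in genes, and the sh-Qk libraries 203477439, 190575293 and 193846939. The first principal component of log2 CPM held 62.4% of the variance and separated the groups. On the second component, with 11.3%, sh-Qk replicate 1 stood apart from the other 2 sh-Qk libraries, at 22.1 against -9.29 and -13.4. All values with an error below are means ± SD of 3 libraries per group, and adjusted p-values of genes and exons are from edgeR's quasi-likelihood test.

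Qk itself (gene ID 19317, chromosome 17) fell from 1246 ± 39.1 CPM in sh-control to 509 ± 25.4 CPM in sh-Qk, which is 2.45-fold lower (log2 fold change -1.29, SE 0.04, adjusted p = 4.13e-08). The 3 sh-control libraries held 1287, 1209 and 1241 CPM and the 3 sh-Qk libraries 537, 488 and 502 CPM. The tested cassette exon of Qk, 117 nucleotides long, was included at 99.9% ± 0.08 in sh-control and 99.8% ± 0.14 in sh-Qk (adjusted p = 0.719). Of 3 alternative 3' splice site events of Qk, the isoform named first fell in share from 96.1% ± 0.43 to 91.1% ± 0.75 in 1 event (adjusted p = 0.00406), a difference under the minimum of 10 points. The other 2 did not pass the test, with shares of 94.8% against 94.9% (adjusted p = 0.972) and 89.2% against 92.5% (adjusted p = 0.0582).

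**Figure D1:**
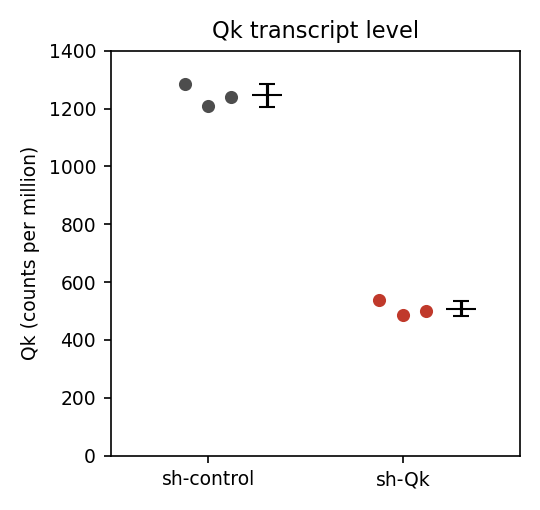
Qk transcript level in CPM (vertical axis, from 0) in each library of sh-control and sh-Qk (points), with the mean ± SD of 3 libraries beside them. The sh-Qk libraries lie between 488 and 537 CPM, all below the sh-control libraries at 1209 to 1287 CPM.

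Among genes that fell, Lgals3, which encodes the lectin galectin-3, fell 6.14-fold (26.1 ± 0.370 to 4.25 ± 0.434 CPM), the transglutaminase Tgm1 5.98-fold (11.96 ± 1.89 to 2.0 ± 0.203), and the serpin Serpina3h 5.28-fold. The siderophore-binding protein gene Lcn2 fell 4.995-fold (20.4 ± 6.06 to 4.09 ± 1.41). The chromatin protein gene Hmga2 fell 4.40-fold, the metalloprotease Adamts14 4.25-fold, and the osteopontin gene Spp1 3.96-fold. The VEGF receptor Flt1 fell 3.91-fold, the interferon-induced Usp18 3.89-fold and the matrix protein thrombospondin gene Thbs1 3.82-fold. Among genes that rose, Ky rose 3.21-fold (4.89 ± 0.644 to 15.7 ± 1.94 CPM), and Dlx1 and Dlx2, homeobox genes of forebrain interneurons, rose 3.12-fold (8.80 ± 0.724 to 27.5 ± 5.004) and 2.74-fold (9.27 ± 0.844 to 25.4 ± 5.49). The urea transporter Slc14a2 rose 3.02-fold, the sulfotransferase Hs3st1 2.93-fold, and Rnf43, a Wnt receptor ubiquitin ligase, 2.72-fold. The phospholipase Plcb4 rose 2.70-fold, the purine salvage enzyme Hprt1 2.53-fold, Asb4 2.45-fold and the cyclooxygenase Ptgs1 2.43-fold. These are the 10 genes in each direction that the fixed rule took, and their adjusted p was at most 0.000182 (Asb4).

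Of 14542 genes tested, 7884 changed (3963 higher and 3921 lower in sh-Qk), and most changes were small. With upper-quartile factors, 3535 rose and 4273 fell, and with at least 1 CPM in every library, 3533 rose and 3669 fell, so the balance of directions depended on these choices. With a minimum of 2-fold, 650 genes remained, of which 544 fell and 106 rose. With a minimum of 0.5 on the log2 scale, chosen after seeing the data, 1372 fell and 573 rose.

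Genes of the extracellular matrix and its receptors fell together: of 44 tested, 28 fell and 8 rose (camera adjusted p = 0.001, but adjusted p = 0.681 with an estimated correlation). Sparc, a collagen-binding matrix protein gene, fell from 864 ± 24.7 to 311 ± 11 CPM (2.78-fold). The laminin chain gene Lamb1-1 fell from 40.5 ± 2.08 to 15.8 ± 0.241, the collagen gene Col6a1 from 18.5 ± 0.988 to 6.996 ± 0.228, and the integrin gene Itgav from 470.0 ± 10.2 to 285 ± 9.37. Of 15 tested fibroblast and mural cell markers, 8 fell and 1 rose (camera adjusted p = 0.0179, adjusted p = 0.681 with an estimated correlation), and 5 members of this list are also in the matrix list. The smooth muscle genes Acta2 and Tagln fell from 42.4 ± 1.37 to 17.5 ± 1.25 and from 26.4 ± 0.466 to 11.1 ± 1.20 CPM. The collagen gene Col1a1 fell from 12.9 ± 1.81 to 6.05 ± 0.810, and the pericyte marker Rgs5 rose from 11.9 ± 0.524 to 15.6 ± 0.872. Of 12 endothelial markers tested, Flt1 fell and Sox18 rose, at 0.0375 ± 0.0357 against 0.170 ± 0.0588 CPM, and 10 did not pass (camera adjusted p = 0.246). The Sox18 call was lost without sh-control replicate 2 (adjusted p = 0.061) and without sh-Qk replicate 3 (0.0771, range over the alternatives 0.008 to 0.0771). Pecam1, at 0.548 ± 0.153 against 0.326 ± 0.112 CPM, passed without sh-control replicate 1 (0.0251) or sh-Qk replicate 3 (0.0203) and with the replicate number as a block (0.0358). Cldn5, at 0.124 ± 0.0295 against 0.0519 ± 0.0423 CPM, passed without sh-Qk replicate 1 (0.0169), with limma-voom (0.0492) and with limma on log2(RPKM + 0.1) (0.0446).

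Type I interferon response genes also fell: of 33 tested, 22 fell and none rose (camera adjusted p = 0.001, but adjusted p = 0.681 with an estimated correlation), with a median log2 fold change of -0.56. The chemokine gene Cxcl10 fell from 19.5 ± 2.62 to 8.88 ± 1.17 CPM, Ifit2 from 32.9 ± 4.16 to 19.5 ± 0.918, Ifit3 from 4.86 ± 1.56 to 1.75 ± 0.211, and Usp18 from 12.7 ± 5.17 to 3.27 ± 0.391. Without sh-control replicate 1 the median was -0.36. Of 7 microglia and macrophage genes tested, P2ry12 fell from 3.87 ± 0.644 to 1.09 ± 0.0849 CPM and Csf1r from 0.0734 ± 0.0197 to 0.0237 ± 0.00501, and 5 did not pass (camera adjusted p = 0.596). Among these was Laptm5 at 0.153 ± 0.0609 against 0.201 ± 0.0577. The Csf1r call was lost without any 1 of the 3 sh-Qk libraries (adjusted p of 0.0531, 0.0812 and 0.0823) and with DESeq2 (0.0895). Over the alternatives it ranged from 0.0202 to 0.542.

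Genes of neuronal commitment rose: of 19 tested, 12 rose and 1 fell (camera adjusted p = 0.00683, but adjusted p = 0.681 with an estimated correlation). The transcription factor gene Sox11 rose from 144 ± 1.94 to 195 ± 0.368 CPM, Insm1, which marks basal progenitors, from 5.76 ± 0.362 to 12.7 ± 1.02. The Notch ligand Dll1 rose from 150 ± 7.25 to 243 ± 16.2, and Rcor2 from 100 ± 4.78 to 124 ± 2.74. RNA-binding splicing regulators rose more often than they fell, with 27 higher and 8 lower of 54 (camera adjusted p = 0.013, adjusted p = 0.681 with an estimated correlation). Among them, 2900083I11Rik, now named Srrm3, rose 4.85-fold (1.08 ± 0.190 to 5.25 ± 0.138 CPM), Rbm9, now Rbfox2, 1.71-fold and Rod1, now Ptbp3, 1.27-fold. Igf2bp2, a binder of growth-related mRNAs, fell 2.50-fold (62.7 ± 2.41 to 25.1 ± 0.198).

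The remaining lists did not pass the camera test. Of 30 neural stem and radial glial genes, 18 rose and 8 fell (adjusted p = 0.127). The glutamate transporter Slc1a3 fell from 1896 ± 3.56 to 985 ± 2.38 CPM, the intermediate filament gene Vim from 5379 ± 222 to 3422 ± 42.8 and the receptor phosphatase Ptprz1 from 4577 ± 95 to 3475 ± 79.0. Notch1 rose from 668 ± 24.7 to 918 ± 35.2. Of 30 neuronal genes, 14 rose and 6 fell (0.0627), with Ina and Mtap2 higher 1.79-fold and 1.36-fold and Stmn2 lower 2.69-fold. Of 25 oligodendrocyte lineage genes, 3 rose and 11 fell (0.0627), among them the precursor marker Pdgfra (904 ± 13.3 to 586 ± 6.21 CPM), Lhfpl3, Ugt8a and the myelin gene Mobp (3.38 ± 0.576 to 0.811 ± 0.269). Of 20 astrocyte genes, 3 rose and 10 fell (0.0627), among them Mlc1 (732 ± 6.60 to 397 ± 13.9 CPM), Acsbg1, Slc4a4 and Cd44. Without 1 library the neuronal list ranged from 0.0293 to 0.12, the oligodendrocyte list from 0.0299 to 0.161 and the astrocyte list from 0.0126 to 0.124. With an estimated correlation the adjusted p of each of these 3 lists was 0.681. The neuronal list passed without sh-control replicate 2 or 3 (0.0293 and 0.0299). The oligodendrocyte list passed without sh-control replicate 1 or 3 or sh-Qk replicate 2 (0.0465, 0.0299 and 0.0368) and with the replicate number as a block (0.043), and the astrocyte list without sh-control replicate 3 or sh-Qk replicate 1 (0.0299 and 0.0126).

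Of 26 p53 target and apoptosis genes, 14 fell and 4 rose (camera adjusted p = 0.138). Ccng1, a p53-induced cyclin gene, fell from 559 ± 19.6 to 161 ± 5.59 CPM (3.46-fold), Gdf15 and Perp fell 3.11-fold and 1.90-fold, and the apoptosome gene Apaf1 rose 1.44-fold. Cell cycle genes were mostly not past the test, with 25 of 40, while 11 fell and 4 rose (0.441). The cyclin genes Ccnd1 and Ccnd2 fell 1.65-fold and 1.36-fold, Cdc2a 1.35-fold, and Tyms rose 1.33-fold. Of 48 adherens junction genes, 15 rose and 18 fell (0.596), with Shroom3 lower 1.77-fold, Rhoa lower 1.57-fold, Fat4 higher 1.56-fold and Mllt4 higher 1.37-fold. Of 60 cytoskeleton genes, 20 rose and 22 fell (0.762), with the linker gene Plec1 lower 2.49-fold, Arhgef11, Evl and Spna2 higher 1.49-fold, 1.37-fold and 1.34-fold. Wnt and Notch target genes split into 10 higher and 7 lower of 23 (0.441), with Rnf43, Nkd1 and Hes1 (1.31-fold) higher and Tcf7 lower (1.42-fold). Of 26 stress response genes, 6 rose and 10 fell (0.325), with Trib3, Asns and Hspa5 lower 2.04-fold, 1.38-fold and 1.25-fold and Psat1 higher 1.19-fold. Of 24 cholesterol synthesis genes, 7 rose and 3 fell (0.501), with Sc4mol lower 1.63-fold and Ebp, Idi1 and Insig1 higher 1.38-fold, 1.33-fold and 1.28-fold. Of 18 genes linked to Qki in other cell types, 5 rose and 7 fell (0.631), with Sirt2 and Add3 lower 1.49-fold and 1.30-fold and Numb and Macf1 higher 1.26-fold and 1.13-fold. Adjusted over the list alone, the counts were equal for 14 of the 19 lists, and moved by at most 2 members in the other 5.

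**Figure D2:**
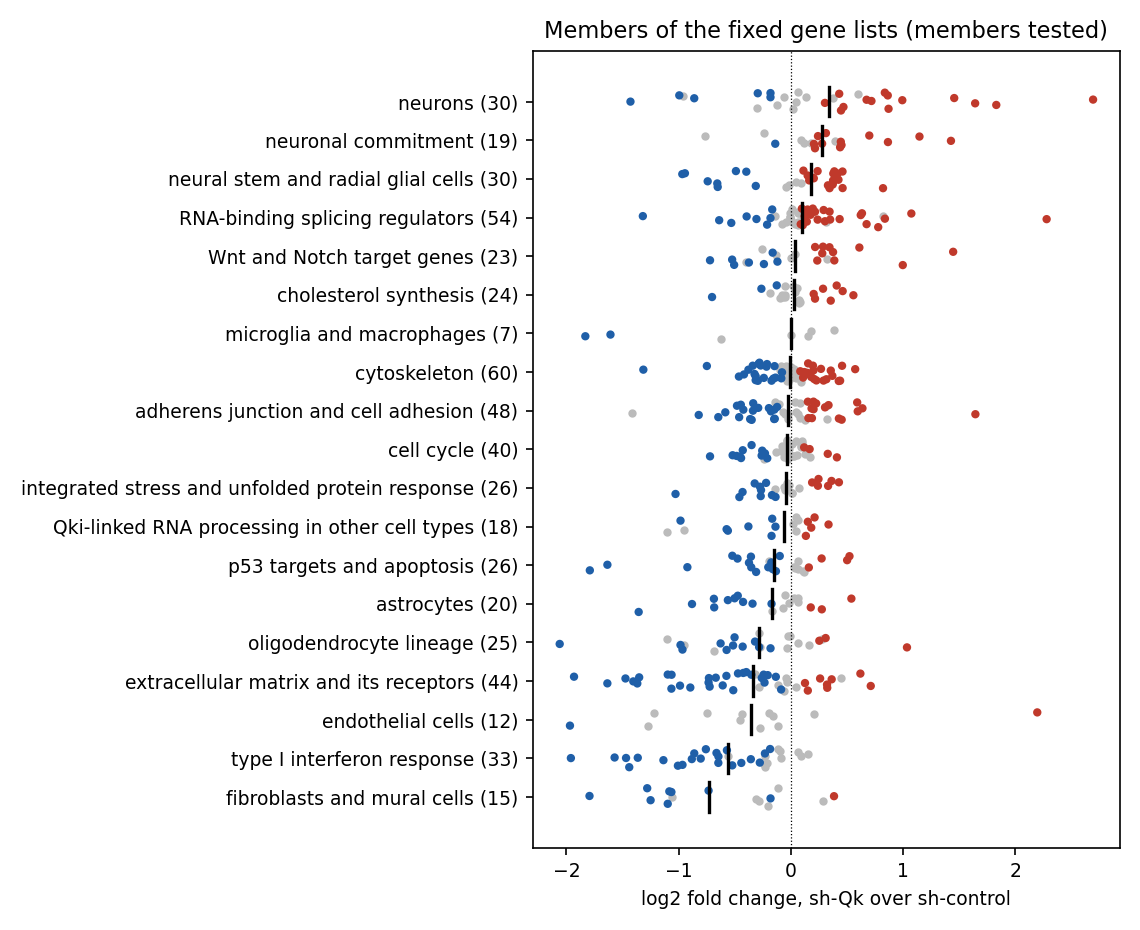
Log2 fold change of sh-Qk over sh-control (horizontal axis) for each tested member of the 19 fixed gene lists (rows, with the number of members tested). Red and blue points rose and fell at an adjusted p under 0.05, grey points did not pass, and black bars are medians, which run from -0.73 for fibroblast and mural cell markers to 0.34 for neuronal genes.

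Exon use changed in both directions, with a median absolute difference of 25.3 points over the called events and at least 50 points in 31 of them (13.3%). The 10 called exons with the largest difference in each direction, by the fixed rule, are given first, not strictly in order of size. A 45-nucleotide coding exon of Pard3, a cell polarity gene (gene ID 93742; event on chromosome 8, mm9 129933456 to 129939696 with its flanking exons), rose in inclusion from 5.64% ± 2.20 to 78.2% ± 7.30 (adjusted p = 0.000901). A 45-nucleotide coding exon of the adhesion gene Nfasc (chromosome 1, 134502061 to 134505083) rose from 3.19% ± 1.96 to 74.3% ± 4.46. Exons of Zdhhc20, Ptpro, Slmap, Rai14, Phkb, the fibronectin gene Fn1, Slc4a4 and Tbc1d23 rose by 49.9 to 71.1 points. In the other direction, an 84-nucleotide coding exon of the lipoprotein receptor gene Vldlr (chromosome 19, 27320025 to 27321579) fell from 81.9% ± 4.03 to 17.7% ± 1.92 (adjusted p = 0.000321). A 63-nucleotide coding exon of the ankyrin gene Ank3 (chromosome 10, 69366946 to 69390565) fell from 89.1% ± 0.97 to 25.6% ± 1.42 (adjusted p = 0.00031). Exons of Lpin1, Ppp1r9a, Mtmr1, Bcas1, Gpm6b and Evi5 fell from 77.7% to 98.7% inclusion in sh-control to 18.3% to 38.8% in sh-Qk. Exons of Stxbp5 (90.3% ± 11.2 to 26.1% ± 3.84) and Sytl2 (98.0% ± 3.46 to 40.2% ± 7.41) also fell, with as few as 65 and 27 junction reads in a library. The calls of 18 of these 20 exons held without any 1 library. The call of Stxbp5 was lost without sh-control replicate 1 or any 1 sh-Qk library, and that of Sytl2 without any 1 sh-Qk library. Both were also lost with the replicate number as a block (adjusted p of 0.135 and 0.0954), and that of Stxbp5 with the second listed junction only (0.136). With the isoform counts as deposited, the differences of Stxbp5, Mtmr1, Gpm6b and Sytl2 were -40.9, -33.5, -35.1 and -36.7 points.

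**Figure D3:**
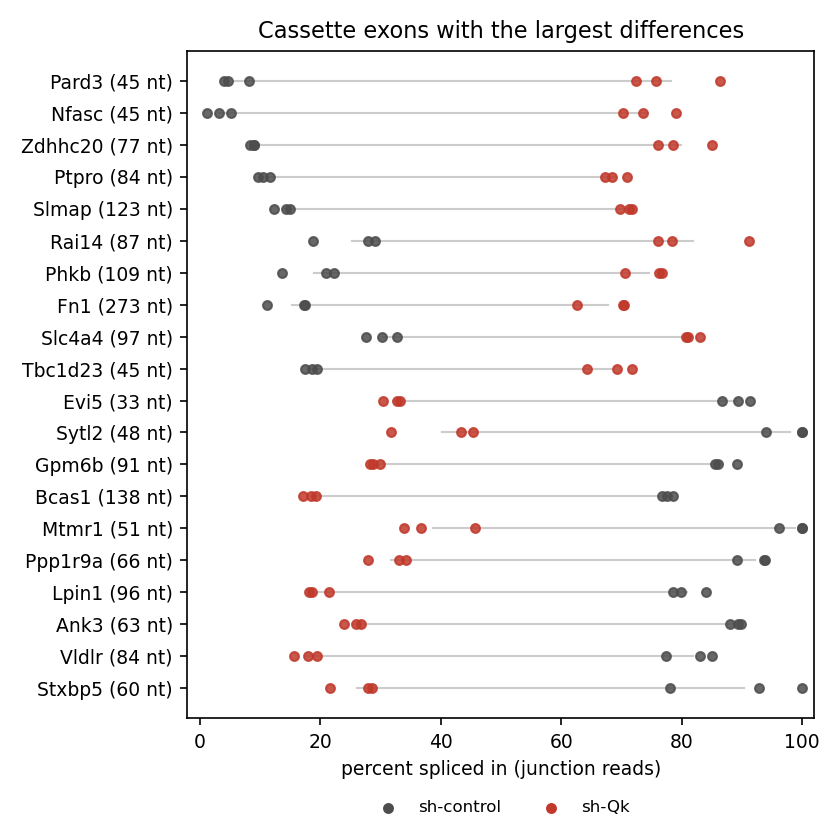
Percent spliced in from junction reads (horizontal axis) in each sh-control library (grey) and sh-Qk library (red) for the 10 called cassette exons with the largest difference in each direction, with exon lengths in nucleotides. Grey lines join the group means, such as 5.64% and 78.2% for Pard3 and 81.9% and 17.7% for Vldlr.

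Of 9062 cassette events tested (8625 exons of 4823 genes, median 374 junction reads per event and library), 233 were called, with 107 more included and 126 more skipped in sh-Qk, in 228 exons of 186 genes. With the isoform counts as deposited, more events were included than skipped (133 and 113). The adjusted p alone was passed by 308 events. Leaving out a library lowered the count by more than 1.5 times in each case: 154, 150 and 154 events were called without sh-control replicate 1, 2 and 3, and 140, 145 and 137 without sh-Qk replicate 1, 2 and 3. Of the 228 exons, 191 matched a wholly coding exon of the same gene by length.

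Changed exons were frequent in genes of the cytoskeleton, where 20 of 52 genes with a tested exon had a called exon (38.5%). Of all 4823 genes, 186 did (3.9%; odds ratio 17.3, 95% interval 9.17 to 32.0, Fisher's exact test, adjusted p = 1.15e-14). With the replicate number as a block, 9 of the 52 genes had a called exon (17.3%, against 1.9% of all genes; adjusted p = 5.38e-06). In 9 of the 20 genes an exon was called without any 1 library, and in 11 the call was lost without at least 1. Besides Ank3, an exon of the actin-capping gene Capzb fell from 54.7% ± 0.60 to 8.38% ± 0.56, an exon of the motor gene Myo6 from 74.7% ± 1.51 to 20.01% ± 0.70, and an exon of the linker gene Dst from 98.9% ± 0.74 to 60.3% ± 2.61. The Dst difference of -38.6 points was -20.4 with the isoform counts as deposited. Of 13 genes linked to Qki in other cell types, 5 had a changed exon (Capzb, Nfasc, Add3, Bin1 and Myo18a; exact test, adjusted p = 0.000566). The Myo18a call was lost without each library except sh-Qk replicate 3 and with the replicate number as a block (0.063). The Add3 exon rose from 13.97% ± 0.68 to 39.1% ± 3.79. The 72-nucleotide Bin1 exon rose from 66.9% ± 0.45 to 83.3% ± 1.59, a call lost without sh-control replicate 1 or 2 or sh-Qk replicate 1 or 2 and with the isoform counts as deposited (9.7 points), the first listed junction only (11.5 points, 0.262) or the replicate number as a block (0.0962).

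Of 6 stem and radial glial genes with a tested exon, 3 had a changed exon (exact test, adjusted p = 0.00485): the matrix gene Tnc (86.5% ± 0.99 to 50.8% ± 1.99), the stem cell surface gene Prom1 (81.3% ± 4.95 to 48.6% ± 4.65) and Ptprz1 (37.7% ± 1.11 to 57.5% ± 2.34). The Tnc difference of -35.7 points was -14.3 with the isoform counts as deposited. The Prom1 call was lost with the replicate number as a block (adjusted p = 0.0698), where 1 of the 6 genes had a changed exon and the list did not pass (0.189). The Ptprz1 call held without sh-control replicate 3 and was lost without each other library and with the block (0.0599). Of 21 adherens junction genes, 4 had a changed exon (adjusted p = 0.0268), among them Pard3, Ptprf (10.8% ± 2.29 to 37.0% ± 2.35) and Ctnna2 (62.6% ± 3.35 to 42.0% ± 1.62). The Ctnna2 call was lost without each of the 6 libraries, with the replicate number as a block (0.168), and with the first or second listed junction only (0.0637 and 0.0538). Of 13 matrix genes, 3 had a changed exon (adjusted p = 0.0339): Fn1 (15.4% ± 3.66 to 67.8% ± 4.48), Fbln2 (3.84% ± 0.45 to 24.2% ± 2.46; 32.2 points with the isoform counts) and Vcan (85.2% ± 1.82 to 59.1% ± 7.38). The Vcan call was lost without each library except sh-Qk replicate 2, and its difference of -26.1 points was -17.0 with the second listed junction only (adjusted p = 0.312) and -0.8 with the isoform counts as deposited. With the replicate number as a block, the Vcan call was lost (0.0696) and the matrix list did not pass (adjusted p = 0.0672). Of 6 oligodendrocyte lineage genes, Bcas1 and Nfasc had one (adjusted p = 0.0467). Genes with a changed exon numbered 15, 51 and 120 in the lowest, middle and highest of 3 equal classes of mean expression. Only the cytoskeleton list was also compared with lists matched on coverage. For the stem cell, adherens, matrix, oligodendrocyte and Qki-linked lists, the exact test therefore cannot separate an excess from an effect of coverage. The adherens, matrix and oligodendrocyte lists did not pass with the calls of limma on the logit (0.0784, 0.079 and 0.0847), a choice made after seeing the data. Over the alternatives these lists ranged from 0.00933 to 0.0784, 0.015 to 0.079 and 0.0228 to 0.0847. The other lists with at least 5 tested genes did not pass: 2 of 33 RNA-binding splicing regulators (Hnrnpa2b1, whose difference of -29.1 points was -1.8 with the isoform counts as deposited, and Rbms1, whose call was lost without any 1 sh-control library or sh-Qk replicate 1 and with the block, 0.0795; list 0.569), 1 of 5 neuronal genes (Mtap2, 0.358), 1 of 6 astrocyte genes (Slc4a4, 0.368), and none of 10 cell cycle, 8 p53 target, 12 interferon, 7 stress response and 14 cholesterol synthesis genes. The neuronal commitment, Wnt and Notch, microglia, endothelial and fibroblast lists had fewer than 5 genes with a tested exon and were not tested.

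Called events of the other types numbered 34 of 678 pairs of mutually exclusive exons, 27 of 2132 tandem cassette exons, 16 of 2258 retained introns, 9 of 5981 alternative 3' splice sites and 6 of 3585 alternative 5' splice sites, 92 in all. Without sh-control replicate 1 or 3 the total was 59 and 60, and without sh-Qk replicate 1, 2 and 3 it was 45, 46 and 51. The 27 calls of tandem cassette exons became 9 and 14 without sh-control replicate 1 and 3, and 4, 5 and 4 without sh-Qk replicate 1, 2 and 3. With the replicate number as a block, 1 was called, as were 3 alternative 3' and 2 alternative 5' splice sites. Mutually exclusive exons had 21 calls without sh-control replicate 2, and retained introns 9 without sh-Qk replicate 2. Alternative 3' splice sites had 3 to 5 calls without any 1 library, and alternative 5' splice sites 2, 3 and 2 without sh-Qk replicate 1, 2 and 3. The tandem cassette of the cadherin gene Fat3 rose in inclusion from 16.7% ± 2.50 to 79.7% ± 1.08, and that of Cd47 from 9.71% ± 4.53 to 55.9% ± 2.53. Both calls were lost with the replicate number as a block (adjusted p = 0.0977 each), and that of Cd47 also without any 1 sh-Qk library. Among mutually exclusive exons, the share of the isoform named first rose from 21.6% ± 2.59 to 69.9% ± 4.24 in Dock9 and from 43.5% ± 0.79 to 83.5% ± 1.05 in Ctage5. The retained isoform of an intron of Hps5 rose from 56.6% ± 0.84 to 82.4% ± 0.89, and that of Vldlr fell from 68.4% ± 2.34 to 36.1% ± 8.69. These events of Hps5 and Vldlr span the regions of called cassette exons of the same genes, as do those of Ctage5 and Cd47. At alternative splice sites, the isoform named first rose from 66.8% ± 1.05 to 93.6% ± 0.86 in Acsl4 and from 8.29% ± 1.5 to 26.6% ± 1.87 in Add1.

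Genes with a changed exon also changed in level more often than other genes. Of the 186, 137 changed in level (73.7%), against 61.7% of the other genes tested in both (odds ratio 1.74, 95% interval 1.24 to 2.47, Fisher's exact test p = 0.000879). Within 3 equal classes of mean expression, the odds ratio by the exact test was 1.33 in the lowest (p = 0.616), 2.08 in the middle (p = 0.0368) and 1.24 in the highest class (p = 0.355), so the relation did not pass the test in the lowest and highest classes.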

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

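The divisor of 510, the log2 minimum of 0.5, 1 event per exon, 1 dispersion and the lists on limma logit calls were chosen after the result was seen. No named gene or exon reversed under any alternative run. The fall of Qk held in every alternative run, in direction and call. The number of changed genes stayed within 1.5 times of 7884 under other size factors, tools, filters, units and left-out libraries (6752 to 7968 without 1 library), and only a minimum fold change moved it: 650 genes (106 higher, 544 lower) at a log2 fold change of at least 1, and 1945 (573 higher, 1372 lower) at 0.5, the latter chosen after seeing the data. Fewer genes pass these by construction. Of 1475 values of named genes under alternatives, 1457 kept their call. The calls that changed include those of Sox18, Csf1r, Pecam1 and Cldn5, which are below 1 CPM.

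Splicing calls depended more on the number of libraries. Without 1 library, 137 to 154 cassette events were called (62 to 75 more included, 74 to 85 more skipped), and 45 to 63 events of the other types. An adjusted p under 0.01 left 129 (60 and 69), a minimum of 20 points left 71 more included and 45 events of the other types, and Fisher's exact test on summed counts, which ignores the spread between libraries, gave 512 (242 and 270). With the isoform counts as deposited, which include the exon body, 246 were called, of which 133 were more included and 113 more skipped, so the balance of directions turned. Of these, 199 were called with junction reads too, and 1 had the opposite direction. The list tests on expression fell from 5 lists to 0 with an estimated correlation and ranged from 5 to 8 without 1 library, with 8 without sh-control replicate 3. The list tests on exons gave 3 lists with limma on the logit. The overlap of level and exon changes had odds ratios of 1.33 and 1.24 in the lowest and highest classes of expression. The cause of these shifts was not tested, except that fewer libraries give less power.

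The labels and the correlations did not settle whether replicate numbers pair the libraries. Same-numbered libraries deviated together with correlations of 0.094, 0.03 and 0.12 in expression and -0.015, -0.01 and -0.016 in splicing, although in expression every library correlated best with its own number, which is a hint from the data only. With the replicate number as a block, 8485 genes and 111 cassette events (50 more included, 61 more skipped) were called, with 55 events of the other types. The stem cell and matrix lists among changed exons no longer passed (0.189 and 0.0672), and the oligodendrocyte list passed on expression (0.043). Of the 27 tandem cassette calls 1 was left. In the simulation, 8% of 10-point differences were recovered by the adjusted p and direction alone, and the effect of depth was not tested apart.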

Other observations

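The test of macrophage transcripts, the test of scaling, the count of other splits, the test of reading frame and the tests of cytoskeleton genes by sh-control inclusion and without Qki-linked members were chosen after the result was seen, and the other tests before. The test of the motif as the whole cause was added after the motif difference was seen, but before its own value. Changed exons kept the reading frame more often than other exons. Of 228 changed exons, 82.9% had a length that is a multiple of 3, against 48.8% of 3942 other exons at 5% to 95% inclusion (odds ratio 5.09, 95% interval 3.57 to 7.43, Fisher's exact test p = 2.6e-25). Exons of at most 27 nucleotides made up 7.9% of the changed exons (18) and 3.1% of the others (122; exact p = 0.00085). By sh-control inclusion alone the shares were 82.3% of 198 and 49.4% of 3487 exons. The comparison set was not limited to coding exons. As a hypothesis, the changed exons may mostly switch between protein isoforms. The exons of Capzb (113 nucleotides) and Gpm6b (91) have lengths that are not multiples of 3 and matched an exon that is not wholly coding. This does not show whether their proteins change.

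Genes with binding motifs of Qki had lower log2 fold changes on average than genes without. Transcripts with at least 2 copies of ACTAAY (Y is C or T), the Qki recognition motif known from textbook work, in the 3' UTR had a log2 fold change lower by 0.147 (difference -0.147, SE 0.012) than transcripts with none, adjusted for UTR length, GC content and expression (1727 and 7654 genes). The difference grew with the number of motifs, from -0.075 with 1 motif to -0.13 with 2 and -0.161 with 3 or more. At an adjusted p under 0.05, 34.8% of genes with at least 2 motifs fell and 30.6% rose, with no adjustment for UTR length. Of genes with none, 25.8% fell and 31.8% rose. All genes here had a mean of at least 1 CPM and a 3' UTR of at least 50 nucleotides, 12060 genes in all. The heptamer screen and the let-7 test below used the same genes. In a screen of 15946 heptamers in 3' UTRs that used no knowledge of Qki, the lowest t was -7.37, for ACTAATA, followed by TACTAAC, TACTAAT and ATACTAA, while the highest t of any heptamer was 5.79. These values are across genes, which are not independent replicates. Loss of Qki at these sites is a candidate explanation for part of the falls.

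Falls outnumbered rises among changes of at least 2-fold (544 against 106), and 3 explanations were weighed. A shift from scaling stays open: falls made up at least 83.6% of the 2-fold changes under each of 5 scalings or tools, but these moved the median of all genes by at most 0.0233 in size on the log2 scale, too little for a test. Loss of Qki at ACTAAY motifs goes with the motif difference of -0.147, but not as the whole cause among the 12060 genes searched. Those with no motif still had 77% falls among 2-fold changes (141 of 183, 95% Wilson interval 70.4% to 82.5%). The interval excludes the share under 60% that a whole cause needs, while the bound of 75% set for the opposite lies inside it. The use of the interval was chosen after the value was seen. Genes with at least 2 motifs had 91.7% falls (44 falls and 4 rises), with no adjustment for UTR length. A 2-fold fall was seen in 1.8% of genes with no motif and 2.5% of genes with at least 2. The 544 and 106 come from all 14542 genes tested, and genes under 1 CPM were not in this test. An off-target action of the hairpin through its seed stays open: the lowest heptamer t of -7.37 belongs to the Qki motif, and the next unrelated heptamer, ACGTTAA, had -6.28, while the hairpin sequence was not analysed here.

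The fall of interferon genes was set against 2 technical explanations. Macrophages or microglia in the sh-control cultures are argued against, because 8 abundant macrophage genes reached at most 0.141 CPM there (Lyz2), while the median fallen interferon gene lost 5.43 CPM. The microglial gene P2ry12, which is not among the 8, was higher there, at 3.87 CPM against 1.09 in sh-Qk. A single sh-control library with a strong response stays open in part: without sh-control replicate 1 the median log2 fold change was -0.362, against -0.564 with all libraries, and it was -0.68 and -0.578 without replicates 2 and 3. A response to the lentivirus that differs between the viral preparations was not tested, and neither was a direct effect of Qki loss.

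The excess of changed exons in cytoskeleton genes was larger than in lists matched on coverage, although 11 of the 20 genes lost their call without at least 1 library. In 10000 random lists matched on the number of tested events and on depth, at most 13 genes had a changed exon, against 20 observed. The matching used broad classes of depth and pooled genes with many tested events, so it was only approximate. Among genes with an exon at 5% to 95% inclusion in sh-control, such an exon changed in 20 of 41 cytoskeleton genes. For other genes the count was 149 of 2480 (odds ratio 14.86, 95% interval 7.46 to 29.5). Having at least 1 alternative exon in sh-control therefore did not alone account for the excess. The number and depth of such exons were not matched here. The test cannot decide whether the list favours genes with known regulated exons. The list shares 6 members with the list of Qki-linked genes, of which 4 changed, and without these members the odds ratio was 12.53 (95% interval 5.94 to 26.1). A regulation of cytoskeletal isoforms by Qki is consistent with these values, as a hypothesis found on these data.

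Hmga2, Hmga1 (248 ± 20.1 to 69.2 ± 6.69 CPM) and Igf2bp2, whose mRNAs are targets of the let-7 microRNA family, fell 4.40-fold, 3.59-fold and 2.50-fold. Higher let-7 activity was tested as an explanation and was argued against: 1471 genes with a let-7 seed match in the 3' UTR differed from the others by -0.001 (SE 0.011). Hmga1 was chosen after its values were seen.

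With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 7884 genes and 233 cassette events, and the highest of the other 9 splits gave 0 of each with edgeR. At an unadjusted p under 0.05 the other splits gave up to 291 genes and up to 215 cassette events, against 8665 and 1224 in the real split. Each of the other 9 splits puts libraries of both groups on each side. The difference between sh-Qk and sh-control then counts as spread and lowers their calls, so no conclusion is drawn from this contrast.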
